A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

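The series holds 8 samples of budding yeast strain AM1003, in which galactose switches on the HO endonuclease to make a double-strand break. Chromatin immunoprecipitation with an antibody against Rpb1, the largest subunit of RNA polymerase II, gave 4 libraries, with 2 replicates before galactose (0 h) and 2 after 6 h in 2% galactose. The 4 input libraries are part of the design and have no values analysed here. Groups and replicate numbers were taken from the sample titles and treatments. No label says whether replicates came from separate cultures, so the spread between them may be technical.

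Each immunoprecipitated library came as its own list of peak summits, so replicates had not been pooled. Per the submitters' processing notes, the tools named were fastp 0.20.1, Bowtie2 2.2.4, SAMtools 1.10 and MACS2 2.2.7.1, with no role, order or parameter attached. The genome build, the peak threshold and the use of the inputs as control are not given in the sources used here. The deposited score of each summit is a −log10 of a p-value or q-value, as MACS2 writes it, and which of the 2 applies is not stated. The lowest scores were 2.03, 2.16, 2.00 and 2.02 in 0 h replicate 1, 0 h replicate 2, 6 h replicate 1 and 6 h replicate 2. Such a score grows with read depth and was not normalized between libraries, so it served only to rank or filter summits within a library. Read depth is unknown, and a missing summit does not mean that polymerase was absent. Either no peak passed the authors' threshold, or a peak that covers the gene had its summit outside it. No peak in the lists was marked as split into several summits. A summit list also holds no occupancy level, so no fold change was computed.

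Gene names came from the RefSeq table of assembly R64, and no genome sequence was given. Since the build behind the summits was not stated, its positions were first tested against 259 landmark genes, namely ribosomal protein, translation factor, glycolytic and small nucleolar RNA genes, by sliding them in steps of 100 bp over 12000 bp to each side. A chromosome was used for genes where it had at least 10 landmarks and its best shift lay within 500 bp. This held for 8 of 16 chromosomes (II, V, XI, XII, XIII, XIV, XV and XVI), where 62.0% to 95.3% of landmarks had a summit within 250 bp. On 7 others the best shift was 1600 to 9500 bp and at most 25.0% of landmarks had a summit. Chromosome VI had too few landmarks. Coordinates were not converted. Gene results therefore cover 3432 of 6002 nuclear protein-coding genes, a restriction chosen after seeing the data. On the chromosomes used, the match was inferred and not stated by the authors. The mean of the median offsets on the 2 strands reached 252 bp, so distances to a start or stop codon carry an uncertainty of that order. It may be larger locally. With the left and right landmarks of a chromosome taken separately, the best shift was 500 bp on the right of V. It was 400 bp on the left of II and -400 bp on the right of XII. Gained and lost calls depend on where the gene ends lie and share that uncertainty. The distance between the summits of a given gene in different libraries does not depend on it, although the choice of summits within the window does. The landmark lists overlap the tested lists of ribosomal proteins, translation factors and glycolysis, and the small nucleolar RNA genes described below.

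A gene held Rpb1 in a library if a summit lay between its annotated start and end. Gained genes had a summit in both 6 h libraries and in neither 0 h library, and lost genes the opposite. With 2 libraries against 2, no permutation of libraries can give a p below 0.333. Calls were therefore set beside the counts from the other 2 splits of the 4 libraries. Summits were shared when they lay within 250 bp, with chance taken from 100 circular shifts. The 18 gene lists were tested by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 36 tests. The background was genes with no 0 h summit for gains and genes with a summit in both 0 h libraries for losses. These tests run over genes, which are not replicates.

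The arm of chromosome III copied from the break was to be tested by its genes from MAT to the right telomere. Because genes could not be placed there, the test was changed after the data were seen. Summits right of 200 kb in the coordinates of the deposited lists were used instead. MAT was not located in these coordinates, and the best landmark shift on chromosome III was -6800 bp over 7 landmarks. The 200 kb line may therefore not mark the edge of the copied arm. A 6 h locus was the midpoint of a summit of 6 h replicate 1 and the nearest summit of 6 h replicate 2, where these lay within 250 bp, and it was gained if no 0 h summit lay within 500 bp of that midpoint. The displacement of the best-scoring summit of each gene was also added after seeing the data, over genes with a summit in the gene or within 250 bp in all 4 libraries.

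Named genes were fixed by rule before the data were examined. They were the 12 gained and 12 lost genes with the best lower rank of score over the 2 libraries, the 8 best genes present in all 4 libraries, 9 fixed genes and up to 4 gained and 4 lost members of each list. GAL3, HO and RNR3 lie on chromosomes not used for genes and were not analysed here. The part of the rule for genes of the copied arm could not be applied.

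Alternatives comprised a wider gene window, an equal number of summits per library (1074), the better-scoring 50% of summits, all annotated genes, a replicate block, lists matched on coding length (10000 draws) and leaving out each library. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The procedures were tested on simulated summits over the 3432 genes. They recovered 98.8% of 80 genes simulated as gained and 100% of 100 simulated as lost. A simulated displacement of 300 bp was recovered as 308 bp over 64 genes. Each simulated gene had a summit in every library of its group, and the displacement was measured in long genes only. In the data, 62.8% to 75.1% of summits recurred between replicates. The simulation therefore checked the calculation and does not give the accuracy of calls in the data.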

Results

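Rpb1 occupancy was mapped in yeast growing in raffinose and again 6 h after galactose was added to induce the HO break, whose repair proceeds by break-induced replication. The question stated for the series is how polymerase is distributed on genes of the repair template while that replication runs. The 0 h lists held 1186 and 1194 summits and the 6 h lists 1288 and 1074 summits in replicates 1 and 2. Median scores were 7.47 and 7.27 at 0 h and 7.24 and 9.75 at 6 h on the −log10 scale of the peak caller. On the chromosomes where genes could be placed, 711 and 706 summits remained at 0 h, and 762 and 658 at 6 h.

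**Figure D1:**
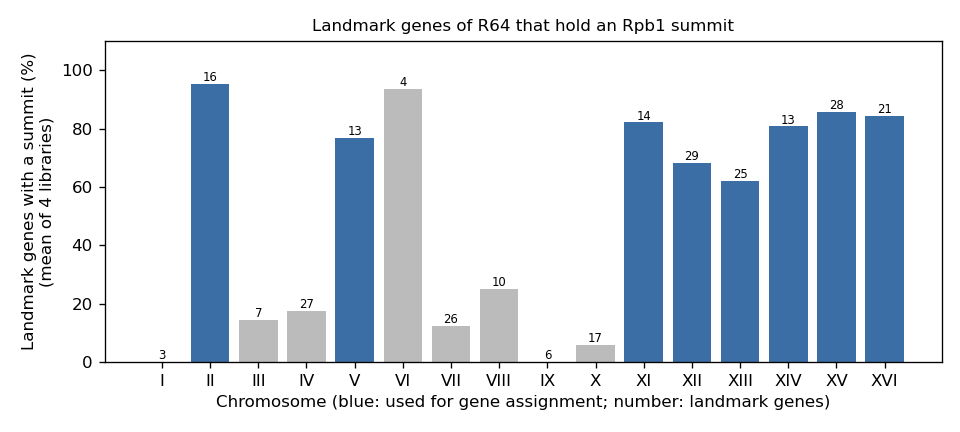
Share of landmark genes with an Rpb1 summit within 250 bp (%, y axis, mean of the 4 libraries) for each chromosome (x axis), with the number of landmark genes above each bar. On the 8 chromosomes in blue the share was 62.0% to 95.3%, and genes were placed only there.

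The sets of Rpb1 sites differed between the time points by more than between replicates. Between replicates, 62.8% to 75.1% of summits had a partner within 250 bp, against 39.2% to 47.0% between 0 h and 6 h. The means were 66.4% and 42.8%, a difference of 23.6 percentage points. Circular shifts of the summits gave mean shares of 4.53% to 5.51%.

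GAL1, GAL10 and GAL2 and 5 ribosome biogenesis genes had Rpb1 summits at 6 h that were missing at 0 h. No 0 h library had a summit within 250 bp of GAL1 (galactokinase), GAL10 (the epimerase of galactose use) or GAL2 (the galactose permease). At 6 h, GAL1 had summits with scores of 87.2 and 131 in replicates 1 and 2, GAL10 of 81.7 and 118, and GAL2 of 86.0 and 147. Several of these lay past the stop codon, as at GAL2 (234 and 217 bp beyond it), so by the gene-body rule only 1 of the 8 placed members of the galactose regulon was gained. That member was GAL80, which encodes the repressor of the regulon, with scores of 6.79 and 4.98. PGM2, encoding phosphoglucomutase, was lost. The list did not pass with gene bodies alone (1 of 6 genes without a 0 h summit, Fisher's exact test, p = 0.145, adjusted p = 1). With 250 bp added on each side, 4 of 6 were gained, against 144 of 2613 other genes (exact p = 0.000135, adjusted p = 0.00242). Without 6 h replicate 2, the gene-body rule gave 4 of 6 from 1 library at 6 h. These were not the same 4 genes, since GAL2 had no summit inside the gene. GAL7, and HUG1 of the DNA damage checkpoint response, had no summit within 250 bp in any library.

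Of 26 placed ribosome biogenesis genes, 5 were gained, namely UTP20, SOF1, IMP4 and ERB1, and RRP5, which is named after its values were seen. The gains were 5 of 13 list genes without a 0 h summit against 70 of 2893 other genes (odds ratio 25.2, Fisher's exact test, p = 1.1e-05, adjusted p = 0.000395). Of all 3432 genes, 2704 held no summit in any library, against 6 of the 26 list members. The test did not match genes on how readily they give a summit. UTP20, a component of the machinery that processes small-subunit ribosomal RNA, had scores of 19.0 and 15.5 at 6 h, and SOF1 had 10.6 and 13.1. Scores were lower at IMP4 (9.10 and 4.99) and at ERB1 (4.41 and 3.97). Members with a summit numbered 9 and 13 at 0 h and 12 and 13 at 6 h. In the same list NOG2, RPA190 and NOP56 were lost, 3 of 9 genes with summits in both 0 h libraries (exact p = 1). With the better-scoring 50% of summits, 3 of 21 list genes were gained and the list no longer passed (exact test, adjusted p = 0.0573).

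In all, 75 genes were gained and 107 lost. The other 2 splits of the libraries gave at most 16 genes in either direction. The gains were 2.58% of 2906 genes without a 0 h summit, and the losses 36.6% of 292 genes with summits in both 0 h libraries. AAH1, which encodes adenine deaminase, had scores of 25.6 and 35.7 at 6 h and no 0 h summit within 250 bp. SMM1 had 22.3 and 37.8, and CSL4, a subunit of the exosome, had 21.0 and 19.6. Of the 75 gained genes, 60 had no summit within 250 bp in either 0 h library. Among the 12 gained genes named by rank, MTC7, POC4, EAF5, PEX30, YLR264C-A and FOL1 had summits within 250 bp in all 4 libraries, DUS4 in some, and 5 were gained with that window too. The highest-ranked genes GRS2 and MTC7 had 6 h summits within 250 bp past the stop codons of TEF1 and HYP2. Up to 500 bp past the stop codon of a gene with a summit within 250 bp in both 0 h libraries, 12 of the 75 gained genes had such summits, including SMM1 beside ACC1 and CSL4 beside PDR16. Adding 250 bp to each gene gave 148 gains and 105 losses. The 105 were partly other genes, since only 54 of the 107 lost genes had no summit within 250 bp in either 6 h library. The better-scoring 50% of summits gave 36 gains and 64 losses. Dropping 1 library relaxes the rule. Gains were 119 without 6 h replicate 1 and 158 without 6 h replicate 2, and losses 196 without 0 h replicate 1 and 169 without 0 h replicate 2.

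At part of the lost genes the summit lay past the stop codon at 6 h. TEF1, encoding translation elongation factor 1 alpha, had its best summit 901 and 735 bp from the start codon at 0 h and 1547 and 1570 bp from it at 6 h. HYP2, encoding translation factor eIF5A, went from 285 and 392 bp to 611 and 615 bp. The ribosomal protein gene RPL10 went from 313 and 213 bp to 787 and 809 bp, and RPP0 from 240 and 258 bp to 970 and 998 bp. The cell wall gene CWP2 went from 102 and 87 bp to 349 and 335 bp. Of the 107 lost genes, 35 had a summit within 250 bp past the stop codon in both 6 h libraries, and 54 had none within 250 bp of the gene in either. NCW1, a cell wall protein gene with 0 h scores of 72.7 and 74.0, and ACC1, which encodes acetyl-CoA carboxylase and had 31.2 and 26.6, were among those without one, although the SMM1 summits lie within 500 bp past the ACC1 stop codon.

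Ribosomal protein genes gave 21 losses and 0 gains among 80 placed members. Of these 21 genes, 18 had a summit within 250 bp past the stop codon in both 6 h libraries. The losses were 21 of 45 genes with summits in both 0 h libraries against 86 of 247 other genes, and this excess did not pass (odds ratio 1.64, Fisher's exact test, p = 0.134, adjusted p = 1). With 250 bp added, 57 of the 80 genes had a summit in all 4 libraries and 5 were lost.

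Genes of respiration and the TCA cycle had 7 losses and 0 gains among 27 placed members, including ACO1 (aconitase), CIT1 (citrate synthase), RIP1 and SDH2. ACO1 had 0 h scores of 15.4 and 14.5, and CIT1 of 12.4 and 9.96, and none of the 4 had a 6 h summit within 250 bp. With gene bodies the list did not pass (7 of 11, Fisher's exact test, p = 0.106, adjusted p = 1). With 250 bp added, 8 of 14 were lost against 97 of 519 other genes (exact p = 0.00187, adjusted p = 0.0224). With 500 bp added, 5 of 20 were lost and the list did not pass (exact test, adjusted p = 0.868). Among glucose-repressed genes, 2 of 12 were lost, ALD4 (aldehyde dehydrogenase) and ICL1 (isocitrate lyase).

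None of the remaining lists passed in either direction with gene bodies (Fisher's exact test, adjusted p = 1 for each). Translation factors had 3 losses among 18 placed members (TEF1, HYP2 and SUP45), and 9 had summits in all 4 libraries. Amino acid synthesis genes had 1 gain (LEU9) and 4 losses (ARO4, SAM1, MET17 and LYS9) among 26. Sterol and membrane genes had 3 losses among 12 (ACC1, ERG10 and ERG5), cell wall genes 2 among 17 (CWP2 and CWP1), and proteasome genes 2 among 16 (PRE1 and PUP1). Glycolysis and ethanol formation had 1 loss among 8 (GPM1), and stress and chaperone genes 1 among 21 (UBI4). The DNA damage response list had 0 gains and 0 losses among 13 members, and 11 of these held no summit in any library. Histones, with 8 members, the G1 and S phase list with 14, the G2 and M phase list with 11, the M to G1 list with 9 and the mating list with 7 had 0 gains and 0 losses. The DNA damage, G2 and M phase and mating lists had 0 genes with summits in both 0 h libraries, and histones had 1. No loss could therefore be found in those 3 lists, and their 0 losses say nothing about change. Unadjusted p-values for these 6 lists were at least 0.3003 by the exact test, where a test was possible.

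Summits sat further towards the 3′ end of genes at 6 h. The median relative position inside genes, from 0 at the start codon to 1 at the stop codon, was 0.578 ± 0.00076 (SD, n = 2) at 0 h and 0.784 ± 0.022 (SD, n = 2) at 6 h. The difference of 0.206 exceeded the spread between replicates, although an exact permutation of 2 against 2 libraries cannot give a p below 0.333. Summits outside genes also became more frequent. The share inside genes was 63.2% and 66.7% at 0 h and 55.9% and 52.0% at 6 h, while the share between convergent genes was 17.0% and 16% against 21.4% and 22.2%, and the share between genes in tandem was 16% and 13.9% against 20.6% and 23.3%.

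**Figure D2:**
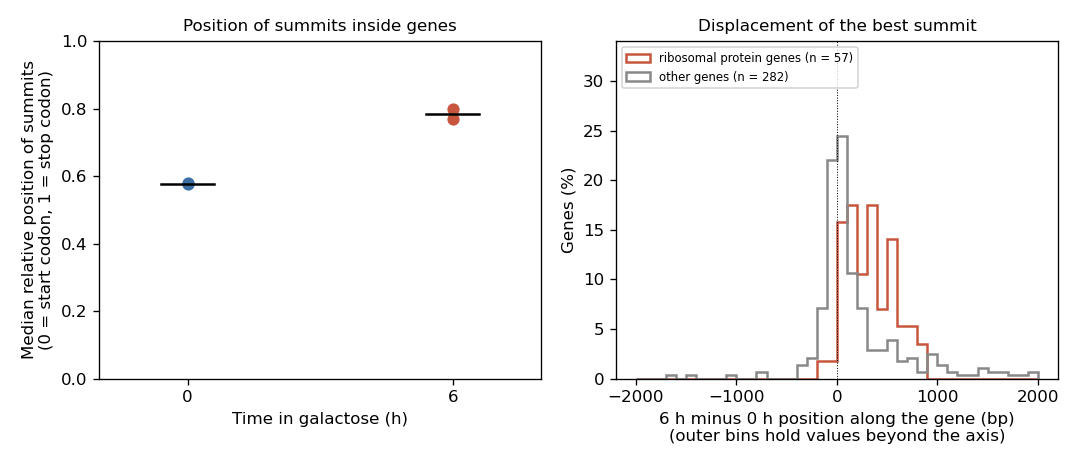
Left, median relative position of summits inside genes (y axis) for each library by time in galactose (h, x axis), with lines at the means of 0.578 and 0.784. Right, percent of genes (y axis) by the 6 h minus 0 h position of the best summit (bp, x axis) for 57 ribosomal protein genes and 282 other genes. The ribosomal protein genes lie further to the right, with a median of 315 bp against 56.0 bp.

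The same 339 genes could be followed in all 4 libraries when 250 bp were added. Their best summit lay a median of 84.5 bp further downstream at 6 h, with quartiles of -11.3 and 369 bp. Using the better-scoring 50% of summits left 169 genes with a median of 147 bp. The median signed difference between replicates was -7 bp at 0 h and 0 bp at 6 h, and the median absolute difference 96.0 and 78.0 bp. In 138 genes both 6 h summits lay downstream of both 0 h summits, and in 35 genes upstream. The other 2 splits gave at most 45 genes in either direction. In ribosomal protein genes the median was 315 bp, against 56.0 bp in 282 other genes (permutation test over genes, two-sided, p = 4e-05 with 100000 resamples). By the sign of the displacement alone, 55 of 57 ribosomal protein genes and 183 of 282 other genes moved downstream. Both 6 h summits lay downstream of both 0 h summits in 43 of the 57 and upstream in 1. Among the 282 other genes these counts were 95 and 34. In that window 66 of the 339 genes shared a best summit with another gene, often with the opposite sign. Without them the median was 142 bp over 273 genes, and 341 bp in 54 ribosomal protein genes against 83.5 bp in 219 others (permutation test over genes, p = 0.0002). Other lists were not tested. Ribosomal protein genes did not have the largest median. By the same measure it was 559 bp in 8 amino acid synthesis genes and 467.5 bp in 7 sterol and membrane genes. It was 452.5 bp in 8 ribosome biogenesis genes and 407 bp in 5 glycolysis genes. Medians were lower in translation factor (274.5 bp), cell wall (247.5 bp), M to G1 (148.5 bp) and proteasome genes (-2.5 bp). Medians between a 0 h and a 6 h library were 204 to 513 bp in 8 amino acid synthesis genes and 153 to 387 bp in 13 translation factor genes. They varied more in 8 ribosome biogenesis genes, from 36.5 to 496 bp, and in 5 glycolysis genes, from -32 to 1304 bp, where replicates differed by a median of 523 and 562 bp. In 5 M to G1 genes they ran from -365 to 464 bp. The range was 419 to 662 bp in 7 sterol and membrane genes and 68 to 248 bp in 9 cell wall genes. In 10 proteasome genes the medians between libraries were 6 to 34.5 bp, but only 5 of the 10 genes moved downstream. TEF2 and YEF3, present in all 4 libraries, showed the downstream displacement too. The YEF3 summit, in the gene for elongation factor 3, went from 530 and 338 bp to 1853 and 2692 bp from the start codon. PDR5, a drug efflux pump gene, went the other way, from 3772 and 3780 bp to 3269 and 2105 bp. The serine synthesis gene SER3 had summits 37 and 54 bp from its start at 0 h and 82 and 201 bp from it at 6 h.

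On chromosome III, where the break lies, new summits at 6 h were concentrated in the right part. Right of 200 kb, the 0 h libraries had 7 and 8 summits and the 6 h libraries 17 and 13, or 7.5 ± 0.71 against 15 ± 2.8 (SD, n = 2). Left of 200 kb the counts were 24 and 21 at 0 h and 26 and 23 at 6 h. Of 10 loci found in both 6 h libraries on the right, 8 had no 0 h summit within 500 bp of the midpoint of their 6 h summits, against 208 of 799 loci elsewhere (80% against 26.0%, two-sided Fisher's exact test, p = 0.000625, adjusted p = 0.0025 over 4 tests). Measured from the replicate 1 summit in place of the midpoint, the locus at 224611 bp was not gained, which left 7 of 10 (exact p = 0.00484). On the left, 3 of 18 were gained (exact p = 0.43). No locus of the right part was lost, among 5 found in both 0 h libraries.

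The 8 gained loci lay at 204748, 214736, 216570, 222828, 224611, 234994, 258204 and 280872 bp of chromosome III, in the coordinates of the lists, whose build is not stated. Their median score in replicate 1 was 5.78, against 6.79 for gained loci elsewhere. In replicate 1 they ran from 2.55 at 222828 bp to 9.16 at 234994 bp, and in replicate 2 from 3.81 at 258204 bp to 12.5 at 234994 bp. A strong site at 287783 bp was present throughout, with scores of 98.7 and 103 at 0 h and 52.1 and 88.5 at 6 h. Using the better-scoring 50% of summits left 2 loci on the right, of which 50.0% were gained (exact p = 0.455). The boundary was chosen after seeing the data, and the names of the genes at these loci were not analysed here.

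**Figure D3:**
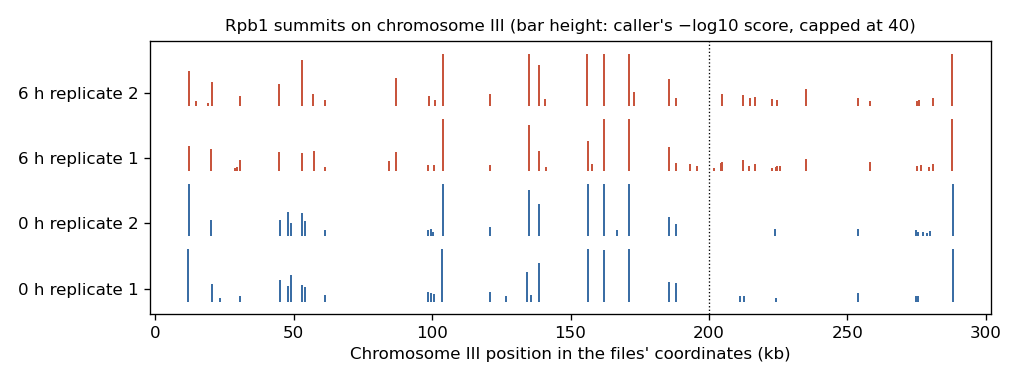
Rpb1 summits of the 4 libraries along chromosome III (x axis, kb in the coordinates of the lists), with bar height giving the −log10 score of the caller, capped at 40, and a dotted line at 200 kb. Right of the line there are 7 and 8 summits at 0 h (blue) and 17 and 13 at 6 h (red).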

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

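The 500 bp gene window, the locus-based form of the chromosome III comparison with its boundaries, search distances and locus positions, and all values of summit displacement and the wider neighbour rule were chosen after seeing the data. Of 62 alternative values of results other than gene lists, 50 kept their direction and, where tested, their side of the threshold, or moved by no more than 1 SD between replicates (1.5 times for counts of genes). No such tally is informative for gene lists, where 161 of 397 values rest on fewer than 5 genes. The count of gained genes went from 75 to 148 with 250 bp added and 171 with 500 bp added, and to 36 with the better-scoring 50% of summits, which also took the 107 lost genes to 64. Without each library in turn, gains ranged from 88 to 158 and losses from 133 to 196, since a rule over fewer libraries is easier to meet. By the exact test, the galactose regulon passed with 4 gained genes at 250 bp (adjusted p = 0.00242) and with 3 at 500 bp (adjusted p = 0.0359). Without 6 h replicate 2, the regulon had 4 gains by gene bodies, which were not the same 4 genes as at 250 bp. Over the leave-outs its gains were 1 to 4. Respiration genes passed as lost at 250 bp with 8 genes, and not at 500 bp with 5 genes. Ribosome biogenesis no longer passed with the better-scoring 50% of summits, with 3 genes. Ribosomal protein genes turned to fewer losses than other genes at 500 bp, with 1 loss (exact test, adjusted p = 0.00681), a window that takes in summits past the stop codon. The position difference was 0.236 with the better-scoring 50% of summits. The chromosome III share was 50.0% with that filter, where 2 loci remained. The cause of the other changes was not tested.

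Replicate numbers are shared between time points, but the correlation of same-numbered deviations over genes was -0.0024, so they were not treated as pairs. With a replicate block, the mean count within same-numbered pairs was 168 gained and 233 lost genes, because only 1 library per time enters each pair. In an exact conditional test under the block, which counts each gene in both pairs and so gives p-values that are too small, the galactose regulon passed as gained (mean 2.5 genes) and amino acid synthesis as gained (mean 3 genes), while translation factors had fewer losses than other genes (mean 4 of 14 genes, odds ratio 0.30). The position difference under the block was 0.206. For the displacement, the filters on summits only drop genes. The chromosome III share of 80% was 60% with a 1000 bp search, 61.5% without 6 h replicate 1 (exact p = 0.0383), 64.7% without 6 h replicate 2 (exact p = 0.0209), 69.9% under the block and 70% from the replicate 1 summit. The other settings that passed gave 77.8% to 90%, with 87.5% without the last 20 kb before the rightmost summit. Gene sets matched on length were not run there because genes could not be placed. Read depth is unknown.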

Other observations

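Fewer small nucleolar RNA genes, which guide ribosomal RNA modification, had a summit within 250 bp at 6 h. Of 53 placed genes, 41 and 41 had such a summit at 0 h, and 35 and 32 at 6 h. On chromosome XIII, a lost locus at 297586 bp lay nearest to SNR77 and a gained locus at 298650 bp nearest to SNR72, both of this class. Whether summits were lost or moved out of the window was not tested. Transfer RNA genes, transcribed by RNA polymerase III, had summits within 250 bp at 9 and 6 of 142 genes at 0 h and at 13 and 14 at 6 h. Summits between divergent genes were 3.80% and 3.40% of summits at 0 h and 2.10% and 2.58% at 6 h.

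The tests in the following paragraphs were chosen after the result was seen, except the 250 bp neighbour test for ribosome biogenesis genes. Summits lay further downstream at 6 h. A constant offset between the files would move Watson and Crick genes in opposite directions along transcription, but the medians were 83.0 and 92.8 bp downstream. The 6 h libraries had more summits (1288) and fewer (1074) than both 0 h libraries, and all 4 medians between a 0 h and a 6 h library were at least 56.0 bp downstream, which argues against the number of called summits. In 91 genes with no neighbour within 500 bp past the stop codon the median was 95.0 bp, against median signed replicate differences of -15 and -11 bp. The median absolute replicate differences were 98 and 101 bp. Both 6 h summits lay downstream of both 0 h summits in 32 of these genes and upstream in 12, and the other splits gave at most 15. This argues against neighbours past the stop codon as the whole cause. Neighbours on the start codon side were not tested in this way. A candidate explanation is that polymerase accumulated nearer the 3′ ends of these genes. Galactose, time and the break itself cannot be told apart as its source, since 0 libraries had galactose and no break.

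For gained loci on chromosome III right of 200 kb, the exact p was 0.00181 with equal numbers of summits. This test says little about the number of called summits, because the means were 1190 at 0 h and 1181 at 6 h. Loci elsewhere were not matched on score, so no comparison here accounts for the low scores of the gained loci on the right. Among 769 overlapping windows of the same length elsewhere with at least 5 loci, 9, or 1.17%, had as high a percent of gained loci, and these lay on chromosomes IX, XII and XIV. Measured from the replicate 1 summit it was 1.30%. A higher copy number of the copied arm after repair may raise weak peaks there and remains open, since 0 input libraries with values were analysed here. A change in polymerase itself is equally untested.

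Ribosome biogenesis genes had more gained members than other genes, although 9 and 13 members held a summit at 0 h and 12 and 13 at 6 h. Of the 5 gained members, 0 had 6 h summits within 250 bp past the stop codon of another gene that held Rpb1 at 0 h, but with a wider rule of 500 bp UTP20 beside the histone gene HTA2 did, so a neighbouring gene stays open for UTP20. Without counting such genes the excess was 4 of 13 against 59 of 2893 (exact test, adjusted p = 0.00446). This argues only against neighbours that already held Rpb1 at 0 h as the whole cause. The rule cannot see a neighbour first occupied at 6 h, so such neighbours stay open. At SOF1 the 6 h summits lay at -3 and 0 bp from its stop codon, within the 252 bp uncertainty of positions. Lists matched on coding length gave an adjusted p of 0.0072, which argues against gene length. No list was matched on how readily its genes give a summit, so a higher rate of detection in this list stays open. A response of the growth programme to galactose is a possible explanation that the design leaves mixed with time and the break.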
